A study of environmental samples with 10 samples.

How the data were processed

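DNA was extracted from 10 soils with a commercial soil kit, bacterial 16S rRNA genes were amplified by PCR, and the product was labelled with Cy5 and hybridised in a single colour, per the labels' protocols. The deposited files are scanner outputs with the linear intensity and local background intensity of 528 spots per array, in 4 blocks of 11 rows and 12 columns. Per the file headers, the deposited intensities were quantified by a histogram method, were not background subtracted and were not corrected for crosstalk between dyes. Any other step taken by the authors before the intensities were saved is not given in the sources used here.

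Spots lay in runs of 3 replicates, found by comparing frames: 0.114% of runs had an SD over 1 on the log2 scale in this frame, against 23.1% and 22.9% in frames shifted by 1 or 2 columns. Each run was taken as 1 probe. The name column was empty for all spots, so the bacterial group lists fixed beforehand could not be matched to any probe, and the planned result on them was not run. The 15 spots marked by the scanner software were left out. The 16 probes at block corners, bright on every array, were used in the background model and then left out of normalization and tests, a choice made after the files were seen.

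Intensities were corrected with limma's normexp method (version 3.58.1, offset 50, R 4.3.3), the 3 spots were averaged on the log2 scale, and the 10 arrays were quantile normalized over 160 probes. The planned rule for a probe above background, local background plus its SD, could not be used, since local background was 0 at most spots. It was replaced, after the files were seen, by signal over 2 times the array floor, the median of the 160 probes. A second threshold of floor plus 3 robust SD and a threshold of 1% of the corner signal were run as alternatives. Quantile normalization gives every array the same distribution, so the Shannon index is the same for all arrays afterwards and was taken before it. It also stretches arrays with few bright probes, so signal over floor is printed beside normalized differences. A probe below background on every array of 1 side has only a bound. The bound sets the bright side's mean against the dim side's mean of the higher of, per array, the lowest normalized signal among probes above background and the probe's own.

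The array labelled permafrost and the array labelled active layer were compared as values, with a count of log2 differences of 1 or more and no p-value. Each was compared with the mean of the Eureka and Alert groups, and Eureka with Alert, by limma's lmFit and eBayes with Benjamini-Hochberg adjustment over probes. In the comparisons of lone arrays the residual spread came from the 8 pristine arrays. Profiles were compared by Pearson and Spearman correlation and by Bray-Curtis distance (vegan 2.7.1), with vegan's adonis R2 tested exactly over all splits of the 8 pristine arrays, and per-array values by two-sided exact permutation tests. The groups carry no shared replicate numbers in the labels, so nothing was paired. P-values of the comparisons with or between the pristine groups measure the spread between soils of a place. Tests of probes next to a corner probe take probes as units, so their p-values measure no spread between soils. Comparisons, tests, the size threshold, the rule for naming probes and most alternatives were fixed before the data were examined. The rule names up to 12 probes in each direction for the pair, up to 10 in each direction among those past the adjusted threshold for each limma comparison, and the 10 brightest of each lone array and of the pristine mean. Other probes named, such as those next after P71 by p-value and those above background in all soils of a place, were chosen after their values were seen.

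On simulated values with the pristine arrays' means and spreads, 40 of 160 probes changed and 50 runs, the Eureka against Alert test recovered 83.5% of probes changed by 2 and 95.8% of those changed by 4 on the log2 scale, with 1.5 false calls per run. The test of a lone array recovered 72.8% and 88.0%, with 1.68 false calls. The simulation held no batch effect. Its rates are not split by brightness, and 106 of the 160 probes were above background on no array. Bright probes varied more, with Eureka against Alert SEs of 1.22 for P94 and 1.64 for P139 (log2), so the rates may not hold for them. With 40 probes changed the adjusted threshold is also easier to reach than with few changed. Alternatives covered background correction, normalization, a filter on dim probes, averaging of spots, marked spots, each pristine array left out in turn, scan day and slide lot, array weights, a larger size threshold, Eureka as the only reference and an exchange of the 2 files in conflict with their labels. The slide lot was taken from digits in the names of the scanner outputs, which are assumed to be a lot number. The permafrost and active-layer arrays carried no such digits. Scaling to the corner probes, keeping the corner probes, the other thresholds for background, normalizing the pair alone, a variance trend and values within the largest slide lot were added after the data were seen, as were profiles and probe numbers within the largest scan day.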

Results

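Soil DNA from the Canadian high Arctic was hybridised to a small 16S rRNA gene microarray, on which each probe targets the ribosomal RNA gene of a bacterial group and its brightness follows how much of the matching PCR product was bound. The series sets a permafrost soil, ground that stays frozen all year, from a depth of 2 m beside the active layer above it, the surface soil that thaws every summer, and adds 8 other pristine surface soils for comparison. There was 1 array of the permafrost and 1 of the active layer. There were 4 arrays of soils from near Eureka: replicate 1 without further description, replicate 2 from a beach, and replicates 3 and 4 from ditches. There were 4 from near Alert: replicate 1 from a control biopile, replicate 2 without further description, replicate 3 from a vegetated area and replicate 4 from a frost-sorted polygon. Each array was a different soil, so the spread within a place is a spread between sites and years of sampling. Nothing gives the spread of repeated arrays of 1 soil.

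Each array held 176 probes in runs of 3 spots, of which 160 were compared. The other 16, at the corners of the 4 blocks, were bright on every array, and their identity is not given in the files. No probe carried a name in the files used here, so probes are called P1 to P176 in scanning order and are given by position, and no result is stated for any bacterial group. The labels of the permafrost and active-layer arrays are in conflict: the scanner header of each names the other sample of the pair. The recorded assignment is kept and the arrays are called the array labelled permafrost and the array labelled active layer throughout. If the 2 files were exchanged, every permafrost against active-layer difference given here changes sign. The comparisons of these 2 arrays with the pristine soils would then trade places, each belonging to the other soil.

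The floor of an array, the median intensity of its 160 compared probes, was 958 on the array labelled permafrost and 1095 on the array labelled active layer, against 305 to 344 on the 8 pristine arrays. The mean intensity of the 16 corner probes ran from 8081 on Alert replicate 2 to 55067 on Eureka replicate 3, with 26889 on the array labelled permafrost and 53019 on the array labelled active layer. The array labelled permafrost and the array labelled active layer were scanned together on a later day than all 8 pristine arrays, so for any comparison of either with the pristine soils the scanning batch and the soil cannot be told apart. Their labels also give the year 2003, against 2005 to 2008 for the pristine soils, so the year cannot be told apart from these either. The number of arrays, not the number of spots, limits the precision of what follows.

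A probe was taken as above background when its signal exceeded 2 times the floor of its array. The floors of the 2 later arrays were 958 and 1095, against 305 to 344 on the pristine arrays. The same threshold therefore needs a higher intensity on the 2 later arrays. Signal over floor and counts above background are not like for like between them and the pristine arrays. Of the 160 probes, 54 were above background on at least 1 array and 106 on none. P101 (block row 2, block column 1, spot row 4, columns 1 to 3) was the only probe above background on all 10 arrays, at 4.12 to 50.3 times the floor in the pristine soils. P100 (block row 2, block column 1, spot row 3, columns 10 to 12) and P131 (block row 2, block column 1, spot row 11, columns 7 to 9) were above background in all 8 pristine soils and on the array labelled active layer, and not on the array labelled permafrost. At the other end, 23 probes were above background on exactly 1 array. The brightest probes of the pristine soils, as mean signal over floor (SD, n = 8), were P94 at 40.9 ± 30.6, P115 at 29.7 ± 39.3, P131 at 29.3 ± 34.2, P101 at 24.0 ± 17.4 and P100 at 19.6 ± 25.7, followed by P15, P134, P69, P66 and P27 at 15.1 to 10.6. The SD exceeded the mean for all of these but P94, P101 and P27. P15 reached 109 times the floor in Eureka replicate 4 and stayed at 0.99 to 3.19 in the other 7 pristine soils. P66 stood at 33.1 and 50.2 times the floor in the ditch soils, Eureka replicates 3 and 4, and at 0.96 to 1.34 in the other 6.

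**Figure D1:**
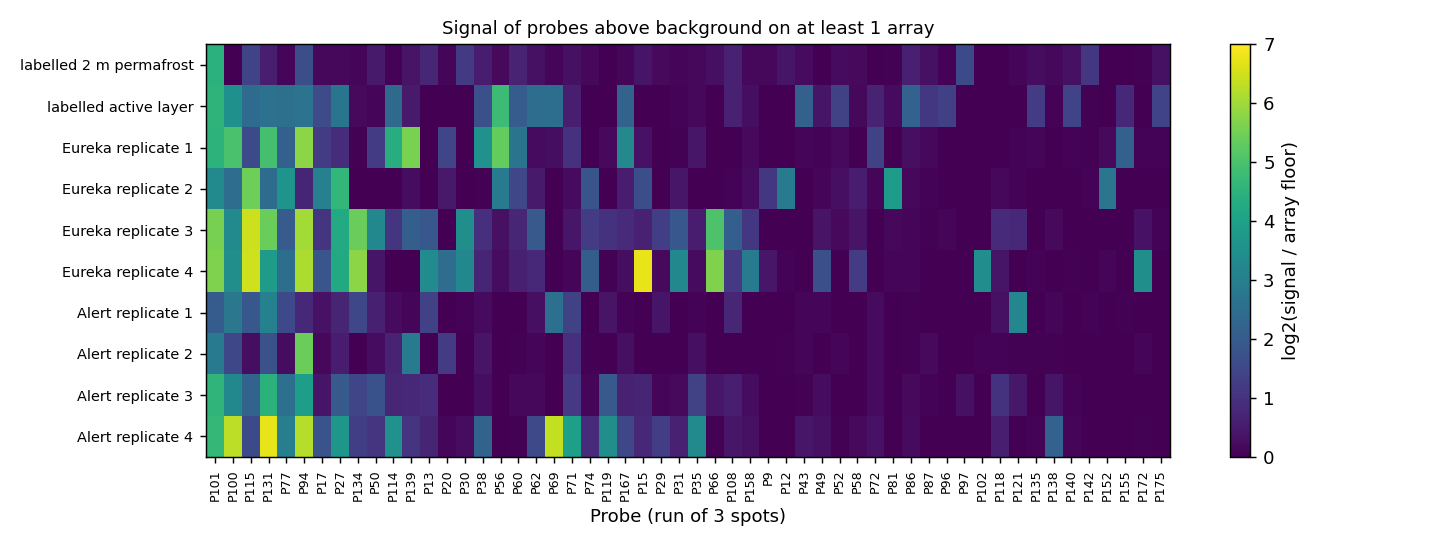
Heat map of signal over array floor (log2 colour scale) for the 54 probes above background on at least 1 array (horizontal axis, ordered by the number of arrays) on each of the 10 arrays (vertical axis). P101 stands above the floor on all 10 arrays, and 23 probes stand above background on exactly 1.

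The first comparison set the permafrost against the active layer above it, the pair the series is about. The array labelled permafrost had 6 probes above background and the array labelled active layer had 23 by the threshold of 2 times the floor, 25 and 33 by a noise threshold (floor plus 3 robust SD), and 17 and 29 by 1% of the corner signal. By the first, 3 of them (P94, P101 and P115) were above background on both. P101 was the brightest probe of the array labelled permafrost, at 22.1 ± 4.06 times the floor (SD over 3 spots of 1 array), close to its 23.6 ± 5.11 on the array labelled active layer. The 5 other probes above background on the array labelled permafrost were dim relative to its floor, with P94 at 3.24, P97 at 2.97, P115 at 2.70, P30 at 2.30 and P142 at 2.20 times the floor. The next 4 in brightness, P13, P60, P108 and P86, stayed below the threshold at 1.70 to 1.55. On the array labelled active layer P56 was brightest at 27.7 times the floor, ahead of P101 and of P100 at 11.3 ± 7.50, a probe whose 3 spots differed widely. P27, P94, P131, P77, P69, P62 and P115 followed at 6.61 to 5.48 times the floor.

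Of the 26 probes above background on either array of this pair, 18 differed by a log2 difference of 1 or more after quantile normalization, 12 lower and 6 higher on the array labelled permafrost. With 1 array of each these differences have no replicate check, and no test of them was made. The split was 3 higher and 22 lower with median scaling, 4 and 14 after division by the total signal, 3 and 15 with scaling to the corner probes and 3 and 22 with no normalization. Over the probes above background by the other thresholds the lean to lower was absent, with 16 higher and 15 lower by the noise threshold and 14 and 15 by 1% of the corner signal. Quantile normalization, used for these counts, makes differences over all 160 probes balance by construction. A wider set of probes is drawn toward that balance, so these counts do not show whether the lean is real. The largest differences toward the array labelled active layer were P56 (block row 1, block column 2, spot row 3, columns 10 to 12) at −6.28, P100 at −6.07, P27 (block row 1, block column 1, spot row 7, columns 7 to 9) at −4.72, P77 at −3.84 and P69 at −3.41. They were followed by P114, P167, P62, P43, P131, P17 and P96 at −2.84 to −1.30. All 12 were below background on the array labelled permafrost, so their differences are only bounded. P56 was at least 5.31-fold, P100 at least 2.18-fold and P27 at least 1.62-fold higher on the array labelled active layer. The other 9 gave no bound above 1 after quantile normalization. With no normalization, where the median difference over all 160 probes was −0.35, the bounds of these 12 ran from 1.40-fold for P96 to 21.4-fold for P56.

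In the other direction, P97 (block row 2, block column 1, spot row 3, columns 1 to 3), P30 (block row 1, block column 1, spot row 8, columns 4 to 6) and P142 (block row 2, block column 2, spot row 3, columns 4 to 6) were above background on the array labelled permafrost and at 0.95, 0.93 and 1.04 times the floor on the array labelled active layer. Their log2 differences were 5.77, 5.03 and 4.39, and they were positive under every scaling tried with the files as recorded. Their bounds after quantile normalization, at least 21.6-, 12.1- and 9.89-fold, rest on stretching a dim array to the distribution of the brighter ones. With no normalization only P97 kept a bound above 1, at 1.31-fold. The 3 remaining positive differences, P115 at 1.85, P60 at 1.51 and P94 at 1.27, turned negative with median scaling, with division by the total, with corner scaling and with no normalization, so no direction is given for them. P115 and P94, above background on both arrays, were 2.78- and 2.69-fold higher on the array labelled active layer with no normalization.

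**Figure D2:**
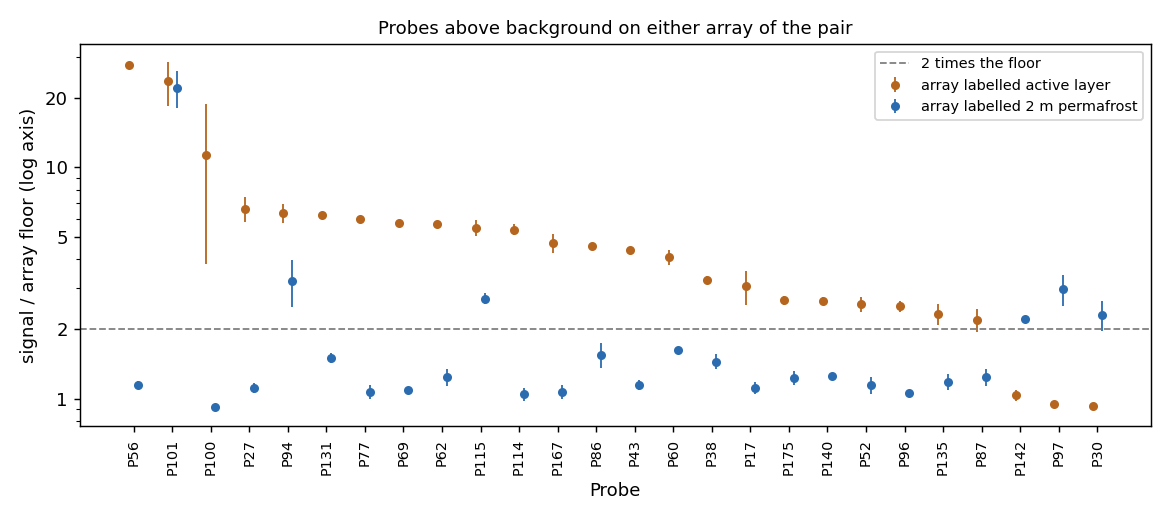
Signal over array floor (log axis) of the 26 probes above background on the array labelled active layer or on the array labelled 2 m permafrost, as means with the SD over 3 spots of 1 array, and a dashed line at the threshold of 2 times the floor. P101 has nearly the same value on both arrays, and P97, P30 and P142 are above the threshold on the array labelled permafrost only.

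Each of these 2 arrays was then set against the 8 pristine soils, the purpose the series gives for them. Of the probes above background on the array labelled active layer, 15 of 23 were also above background in at least 1 pristine soil, with 13 of them in Alert replicate 4, 12 in Eureka replicate 1 and 4 to 10 in each of the others. P97 and P142 were above background on the array labelled permafrost and in no pristine soil, where P97 lay at 0.78 to 1.24 and P142 at 0.92 to 1.05 times the floor. P100 was the reverse case, at 0.92 times the floor on the array labelled permafrost and 2.89 to 79.4 times in the 8 pristine soils.

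By limma, with the lone array assumed to vary like the pristine groups, 8 of 160 probes differed between the array labelled permafrost and the mean of both places at an adjusted p under 0.05. They were 7 higher and 1 lower, and 17 had an unadjusted p under 0.05. P97 was higher by 5.76 ± 0.39 (log2, SE, limma adjusted p = 0.00011) and P142 by 4.63 ± 0.35 (limma adjusted p = 0.00011). Their bounds after quantile normalization, 9.73- and 4.46-fold, rest on stretching an array with few bright probes. Signal over floor of P97 and P142 on this array was 2.97 and 2.20. P100 was lower, with a log2 difference of −5.03 ± 0.67 (adjusted p = 0.00284), at least 1.06-fold. With no normalization these 3 bounds were 3.99-, 2.66- and 2.48-fold, but there the median probe of this array stood 0.743 (log2) above the pristine soils. The other 5 (P86, P125, P8, P140 and P175) were below background on the array labelled permafrost and in all 8 pristine soils, so they carry no fold. All 7 higher probes but P97 and P142 lay next to a corner probe, as do 32 of the 160. The count was 5 (4 higher and 1 lower) with median scaling, where P100 was not among them, 2 (P97 and P100) after division by the total and, under that shift of the median probe, 39 (all higher) with no normalization. It was 1 (P100) over the 31 probes above background on at least 2 arrays, a filter that removes the other 7 before testing. Over the 8 fits with 1 pristine array left out, P175 lost its call in 5, P140 in 1 and the others in none. With corner scaling limma called 0, with 4 at an unadjusted p under 0.05, and the adjusted p was 0.161 for both P97 and P100 and 0.241 for P142. Of the 160 probes, 39 (24.4%) lay outside the range of the 8 pristine arrays, where chance gives 22.2%.

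The same comparison for the array labelled active layer gave 6 of 160 probes, all higher, with 15 at an unadjusted p under 0.05. As limma log2 differences with SE, these were P86 (2.20 ± 0.29, adjusted p = 0.0116), P43 (2.12 ± 0.35, adjusted p = 0.0186), P175 (1.97 ± 0.34, adjusted p = 0.0186), P140 (1.70 ± 0.34, adjusted p = 0.0338), P96 (1.47 ± 0.21, adjusted p = 0.0129) and P135 (1.28 ± 0.25, adjusted p = 0.0338). All 6 were above background on the array labelled active layer, at 2.32 to 4.58 times the floor, and in no pristine soil. All 6 also lay next to a corner probe. After quantile normalization only P86 and P43 had a bound above 1, at least 1.21- and 1.07-fold. With no normalization the 6 bounds ran from 3.31- to 8.11-fold, but there the median probe of this array stood 1.14 (log2) above the pristine soils, and the floor of the 2 later arrays was on average 3.15 times that of the pristine arrays. P56, the brightest probe there, had a limma log2 difference of 5.68 ± 1.69 with adjusted p = 0.19, and was the 1 probe called after division by the total and with corner scaling. The count was 27 (17 higher and 10 lower) with median scaling, 73 (all higher) with no normalization, under that shift, and 2 (P96 and P175) with a variance trend. The filter on probes above background on at least 2 arrays removes all 6, so it tests none of them. By limma the count was 0 without Eureka replicate 4, with 15 at an unadjusted p under 0.05. Over the 8 fits with 1 pristine array left out, P135 lost its call in 5, P140 in 4 and the other 4 probes in 1 each. Probes outside the range of the 8 pristine arrays numbered 41 (25.6%), against 22.2% by chance.

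Eureka and Alert were the only places with replicates. Among the 8 pristine soils, 38 probes were above background in at least 1 Eureka soil and 25 in at least 1 Alert soil, 19 of them in both places, 19 in Eureka alone and 6 in Alert alone. P17, P77, P100, P101, P115 and P131 were above background in all 4 Eureka soils, and P100, P101 and P131 in all 4 Alert soils. By limma 1 of 160 probes differed at an adjusted p under 0.05, and 17 had an unadjusted p under 0.05. That probe was P71 (block row 1, block column 2, spot row 7, columns 7 to 9), at a normalized log2 intensity of 7.95 ± 0.63 in Eureka and 10.8 ± 0.74 in Alert (SD, n = 4 each), a difference of −2.87 ± 0.44 (SE, adjusted p = 0.0384). Its signal over floor was 2.61, 1.92, 2.26 and 15.4 in Alert replicates 1 to 4 and 1.98, 1.15, 1.33 and 1.06 in Eureka replicates 1 to 4, so on that scale the places overlapped. Alert replicate 2, below background, was stretched to 11.1 by the normalization and enters the bound. P71 was above background in 3 of 4 Alert soils and in no Eureka soil, at least 4.01-fold higher at Alert, or 1.69-fold with no normalization, where the median probe stood 0.347 higher in Eureka. The next smallest p-values among probes above background in a pristine soil belonged to P131 (−1.88 ± 0.55), P100 (−1.45 ± 0.45) and P60 (1.67 ± 0.55), with limma adjusted p = 0.396, 0.397 and 0.397. P60 was above background in 2 Eureka soils and in no Alert soil, so its difference is not a measured fold.

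The call of P71 was not stable. Its difference kept its direction throughout, and was −3.10 with adjusted p = 0.163 with the scan day as a block and −3.33 with adjusted p = 0.101 with the slide lot as a block. Within the largest scan day, 3 Eureka and 2 Alert arrays, it was −3.10 with adjusted p = 0.204 (all by limma). The largest slide lot held 3 Eureka arrays and 1 Alert array, so it shows a difference, −3.57, with no spread for Alert. In both blocked fits and within the largest scan day the 1 probe called was P69 instead, which was above background in 2 Alert soils. Leaving out 1 array at a time gave P71 a difference of −3.25 to −2.51 and an adjusted p of 0.0143 to 0.188. That p was above 0.05 when any of Eureka replicates 2, 3 and 4 or Alert replicates 1, 2 and 4 was left out. A second slide lot held 1 array of each place, with P71 at 7.69 in Eureka replicate 3 and 10.7 in Alert replicate 1, and no other scan day or slide lot held both places.

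The profiles as wholes did not separate the places by the test used. In a permutation test on Bray-Curtis distances place took 25.8% of the variation (exact p = 0.0857, where 4 against 4 allows 0.0286 at the smallest). Without Eureka replicate 1 R2 was 0.394 (exact p = 0.0286), and within the largest scan day it was 0.36 (exact p = 0.2, where 3 against 2 allows 0.1 at the smallest, so this p could not fall under 0.05). Over the 160 probes, which are not independent replicates, the median Pearson correlation was 0.53 between Eureka soils, 0.73 between Alert soils and 0.55 between the places. Median Spearman correlations in that order were 0.345, 0.446 and 0.294, and median Bray-Curtis distances 0.479, 0.379 and 0.505, so by these Eureka soils were more alike than soils of different places and by Pearson they were not. The ditch soils, Eureka replicates 3 and 4, correlated at 0.79, and Eureka replicate 3 with Alert replicate 3, from the vegetated area, at 0.81. The array labelled permafrost correlated at 0.44 with the array labelled active layer (0.85 with the corner probes kept in), and at 0.32 to 0.60 with the pristine soils. The closest pristine soil changed with the measure: Eureka replicate 3 by Pearson, Alert replicate 4 by Spearman (0.469) and Alert replicate 3 by Bray-Curtis distance (0.36). The array labelled active layer correlated at 0.44 to 0.76 with the pristine soils, highest with Eureka replicate 1, which was also highest by Spearman (0.479), while the smallest Bray-Curtis distance was to Alert replicate 3 (0.398, against 0.402 for Eureka replicate 1).

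The number of probes above background was 19.0 ± 3.56 in Eureka soils and 12.5 ± 6.35 in Alert soils (SD, n = 4 each), a difference within the spread between soils (two-sided exact permutation p = 0.114, 0.457 after Benjamini-Hochberg adjustment over 4 measures, 0.0286 the smallest possible). Within the largest scan day the difference was 2.5 (exact p = 0.7, 0.1 the smallest possible). The Shannon index of background-corrected intensities was 3.26 ± 0.28 in Eureka and 3.65 ± 0.65 in Alert (exact p = 0.371, adjusted 0.686), 4.03 on the array labelled permafrost and 3.75 on the array labelled active layer, against 2.81 to 4.38 over the pristine soils. Its difference of −0.385 between the places turned to 0.035 over probes above background and 0.087 with corner probes kept in, and was −0.665 to −0.142 with 1 array left out. The index covers all 160 compared intensities, most of them at the floor, so a high value does not mean many positive probes. The array labelled permafrost, at 4.03, had 6 probes above background, while Alert replicate 4, lowest at 2.81, had 21. The number of probes above background moved with array brightness. Over the 8 pristine arrays it correlated with the log2 corner intensity at Pearson r = 0.853 (exact permutation p = 0.00938, adjusted 0.0188) and Spearman rho = 0.826 (exact permutation p = 0.0172, adjusted 0.0343; 2 relations computed). Pearson r was 0.825 without the 2 arrays farthest from the median intensity and 0.815 over the 5 arrays of the largest scan day. With a probe instead counted when its signal over the floor passed 1% of that of the corner probes, r was 0.385 (exact permutation p = 0.344) and rho 0.323 (exact permutation p = 0.434). That threshold rises with the corner intensity, so a weaker relation follows from its construction. The array labelled permafrost then had 17 probes and the array labelled active layer 29.

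**Figure D3:**
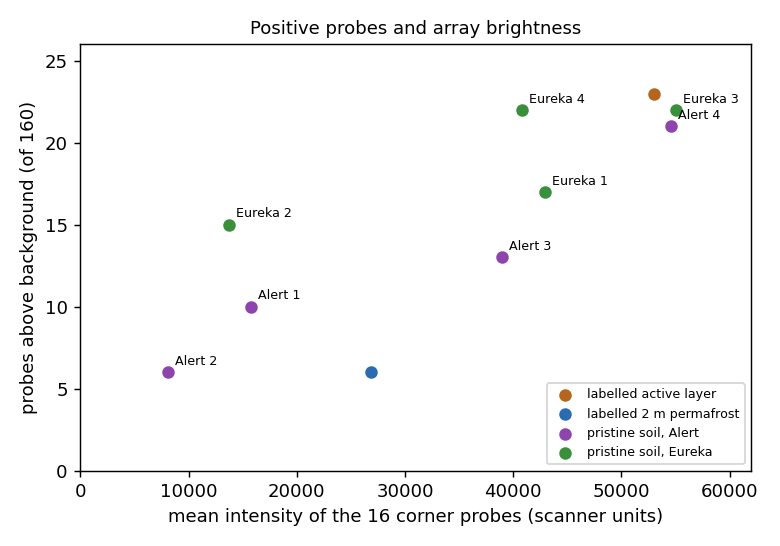
Number of probes above background, of 160, against the mean intensity of the 16 corner probes, in scanner units, with 1 point per array, coloured by group. Among the 8 pristine arrays, named by place and replicate number, the dimmest array has 6 probes above background and the brightest 22; the array labelled permafrost lies at 6 and the array labelled active layer at 23.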

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

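The tests of the pair of arrays, of corner neighbours and of array brightness were chosen after the results were seen, and what the dimming and brightness tests would have to show was changed after their values were known. Dixon's test marked 3 of 64 groups of 4 values, where chance marks about 3.2. P100 stood at a normalized log2 intensity of 12.3 in Eureka replicate 1, above 10.45 to 10.66 in the other Eureka soils. P125 stood at 7.27 in Eureka replicate 3 against 6.81 to 6.84 in the others, all below background. P87 stood at 8.87 in Alert replicate 2 against 7.03 to 7.20 in the others, also below background on all 4 arrays.

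The pair of arrays has a pattern of 20 probes above background on the array labelled active layer only and 3 on the array labelled permafrost only. Of the 32 probes next to a corner probe, 23 were below background on the array labelled active layer. On the array labelled permafrost all 32 were. Other probes below background numbered 114 and 122 on these arrays, in that order. The 8 probes above background on the array labelled active layer and in no pristine soil all lay next to a corner probe. An exchange of the files goes with the headers, since 2 of 2 name the other sample; it would turn every direction and not the sizes. A uniformly dimmer array is left open for the lower probes. The corner probes themselves did not share 1 permafrost over active-layer ratio of intensity minus floor, the measure used for all probes here. Their log2 ratios ran from −3.23 to −0.50 with a median of −0.95, so a comparison with the lowest of them is a weak test. With probes below background taken at the threshold, only 2 of 23, P56 and P100, had a ratio below that of every corner probe. P100 passed narrowly, at −3.28, and its 3 spots on the array labelled active layer differed widely. With ratios as measured, the form first run, 13 of 23 had such a ratio, which rests on noise below background. Uniform dimming is argued against for the 3 probes above background on the array labelled permafrost only. In intensities as deposited their lowest spot there was at least 1.73 times their highest spot on the array labelled active layer. Uniform dimming cannot give this, though a local artefact could. These 3 were picked for being above background on that array alone, which favours a ratio above 1. The difference in soil stays open as the biological account, untested with 1 array of each.

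Probes next to a corner probe stood higher over the floor than other probes among those below background, by 0.167 on the array labelled active layer (permutation p = 1e-04, the smallest 10000 draws can give; adjusted 0.001 over 10 arrays), 0.0794 on the array labelled permafrost (adjusted permutation p = 0.024) and 0.0697 on Eureka replicate 3, the pristine array with the brightest corner probes (adjusted permutation p = 0.004), and the other 7 arrays gave −0.007 to 0.033. Of the 10 probes that limma called higher on either lone array, 8 lay next to a corner probe (5 of 7 on the array labelled permafrost, 6 of 6 on the array labelled active layer), as do 32 of the 160 (Fisher's exact p = 3.92e-05). Spill of light from bright spots is a candidate explanation left open. In units of each array's floor, the 0.0697 of Eureka replicate 3 was near the 0.0794 and far under the 0.167 of the later arrays. Alert replicate 4, with nearly as bright corner probes, gave 0.017. The floor was 344 on Eureka replicate 3, against 958 and 1095 on the later arrays, so these excesses are not like for like in intensity. The corner probes averaged 55067 on Eureka replicate 3 and 26889 on the array labelled permafrost. A different slide or scan batch also stays open, since both later arrays, at 0.0794 or more, exceeded every pristine array. Batch and soil cannot be told apart here, and no biological account of a position effect was tested.

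The number of probes above background moved with array brightness over the 8 pristine arrays. Spearman's rho was 0.826, and a brighter hybridisation is a candidate explanation left open, since each soil had 1 array and brightness and soil are confounded. A difference between the places is left open by an exact p of 0.114 at 4 arrays each. The amount of DNA on each array was not measured here.

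For Eureka against Alert, 2 of the 35 splits of the 8 pristine arrays, the real one included, gave at least the 1 probe called, and the highest other split gave 2, so chance cannot be excluded for P71. The split along the largest slide lot gave 0.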

How the results depend on the processing

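Corner scaling, corner probes kept in, the other thresholds for background, the variance trend and values within the largest slide lot were alternatives chosen after the data were seen. Signal over background limits all of this: most probes sat at the floor, and there normalization sets the differences. The median difference over all 160 probes, array labelled permafrost minus array labelled active layer, was 0.021 with quantile normalization, −0.025 with median scaling, 1.03 after division by the total, 0.849 with corner scaling and −0.35 with no normalization. In the same order it was −0.103, −0.192, 0.962, 0.99 and 0.743 for the array labelled permafrost minus the pristine soils, and −0.017, −0.12, −0.02, 0.189 and 1.14 for the array labelled active layer minus them. No paired analysis was possible because the labels share no replicate numbers between groups. The bacterial group lists were not run under any alternative, since spots carry no names. Normalization cannot change the number of probes above background. The causes of the changes below were not tested, except where the construction of the alternative shows them.

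For the pair, 18 probes differed by 1 or more; 11 did by 2 or more. The count was 31 among probes above background by the noise threshold (16 higher and 15 lower) and 29 by 1% of the corner signal (14 and 15). The array labelled permafrost had 25 and 17 probes above background by those thresholds. P94, P60 and P115 turned to −1.10, −1.82 and −1.15 with median scaling, −0.046, −0.767 and −0.096 after division by the total, −1.43, −2.15 and −1.48 with no normalization, and −0.227, −0.948 and −0.278 with corner scaling. No other difference of 1 or more turned under these. With the 2 files exchanged, all 18 turn by construction: P56 to 6.28, P100 to 6.07, P27 to 4.72, P77 to 3.84, P69 to 3.41, P114 to 2.84, P167 to 2.56, P62 to 2.36, P43 to 1.72, P131 to 1.51, P17 to 1.48, P96 to 1.30, P97 to −5.77, P30 to −5.03, P142 to −4.39, P115 to −1.85, P60 to −1.51 and P94 to −1.27. The correlation of the pair, 0.436, was 0.85 with corner probes kept in.

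Against the pristine soils, the array labelled permafrost had 8 calls, and 5 with median scaling, 2 after division by the total, 39 with no normalization, 1 over probes above background and 0 with corner scaling. Leaving out 1 pristine array gave 7 to 9. The array labelled active layer had 6, and 27, 1, 73, 0 and 1 under the same alternatives, 2 with a variance trend and 0 to 7 with 1 array left out, the 0 being without Eureka replicate 4. The filter on probes above background needs 2 arrays, so by construction it removes every call of both lone arrays but P100. For the probes named in these comparisons, 125 values stayed past the threshold and 28 did not for the array labelled permafrost, and 83 and 31 for the array labelled active layer. None of them changed direction with the files as recorded. With the 2 files exchanged, the results of the 2 lone arrays trade places. The permafrost difference of P100 would go from −5.03 to 1.04 and that of P97 from 5.76 to −0.006.

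Eureka against Alert gave 1 call, and 0 with plain subtraction, no background correction, median scaling, no normalization, only probes above background, or the largest slide lot, where Alert has 1 array and no spread. It gave 3 (P69, P71 and P115) after division by the total and 2 (P69 and P115) with corner scaling. With 1 array left out it gave 0 to 2, with 0 without Eureka replicates 2, 3 or 4 or Alert replicates 2 or 4, 2 (P71 and P100) without Eureka replicate 1, and P35 instead of P71 without Alert replicate 1. By limma these counts of 0 went with 3 to 23 probes at an unadjusted p under 0.05. The profile R2 of 0.258 was 0.34 (exact p = 0.0286) with corner probes kept in, and 0.231 to 0.394 with 1 array left out, with an exact p under 0.05 only without Eureka replicate 1. The difference in probes above background was 4.33 to 9.33 with 1 array left out. The Shannon difference, −0.385, was 0.035 over probes above background and 0.087 with corner probes kept in, and −0.665 to −0.142 with 1 array left out.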

Other observations

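The probes in this part were chosen after their values were seen, and their differences were not tested. Several probes separated the ditch soils, Eureka replicates 3 and 4, from most others. P134 (block row 2, block column 2, spot row 1, columns 4 to 6) stood at 42.5 and 55.0 times the floor there, and at 0.99 to 2.85 in the other 6 pristine soils. P115 stood at 88.7 and 89.6 in the ditch soils and at 43.8 in the beach soil, Eureka replicate 2, against 1.20 to 4.66 in the other 5. P30, which was above background on the array labelled permafrost, stood at 10.9 and 9.63 in the ditch soils and at 0.90 to 1.17 in the other 6 pristine soils.

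Eureka replicate 1 and the array labelled active layer shared P56, at 40.8 and 27.7 times the floor, while P56 stood at 7.27 in the beach soil and at 0.97 to 1.24 in the other 6 pristine soils. P114 stood at 20.4 in Eureka replicate 1, 11.7 in Alert replicate 4 and 5.39 on the array labelled active layer, and P167 at 9.89, 2.81 and 4.70 on the same arrays. P139 stood at 48.4 in Eureka replicate 1 and at 1.41 on the array labelled active layer.

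Some probes were bright in few soils. P69 reached 82.0 times the floor in Alert replicate 4, from the frost-sorted polygon, with 5.89 in Alert replicate 1 and 0.91 to 1.20 in the other 6 pristine soils, and 5.77 on the array labelled active layer. Above background on 1 array only, P81 and P12 stood at 14.4 and 7.42 in the beach soil, P121 at 9.44 in the control biopile soil, and P102 and P172 at 10.8 and 11.2 in Eureka replicate 4.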
